A study of Drosophila melanogaster with 10 samples.

How the data were processed

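Transcript levels were measured with Affymetrix Drosophila expression arrays on biotin-labelled total RNA from 10 samples. The Kc samples were a Drosophila cell line of embryonic origin with haemocyte-like properties, and the others were salivary glands, the secretory organ of the larva. Per the labels, Kc cells were exposed to dsRNA against GFP or against the linker histone H1 for 1 hour without serum on days 0, 2 and 4, and RNA was taken on day 6, whereas the series record states a single RNAi treatment. Per the labels, the glands came from flies that expressed an RNAi construct against nau or against H1 under a ubiquitous driver, with crosses kept at 18 °C and knockdown at 29 °C from the embryo on. Each Kc group had 2 arrays and each gland group had 3. The labels give each array a letter and do not state whether the arrays of a group came from separate cultures or animals, so the p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

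The deposited values were 1 intensity per probe set and array on a linear scale, and RMA is the only tool the submitters' processing notes name, with no version and no account of whether cells and glands were processed together. The authors' intensity values ran from 4.39 to 20761 over the 10 arrays, with no negative value, so log2 of the deposited intensity was taken before any test. Array medians lay between 4.11 and 4.31 on the log2 scale. The table held 18952 probe sets. The 183 Affymetrix control probe sets were left out of the tests and described separately, which left 18769. Of these, 13647 carried 1 gene symbol in the platform annotation, 401 carried several and 4721 carried none. Probe sets with several symbols were named only as a family where all symbols belonged to 1 family. For 14432 of 14553 gene entries a match by gene number was found in the RefSeq annotation of assembly Release 6, which was used for names and for the order of genes only, and 0 symbols changed. Since the files used here name no genome build, no coordinates are given and shares per chromosome arm were not tested. A gene with several probe sets was represented by the probe set with the highest mean over the 10 arrays, which gave 11982 named genes.

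A linear model with a mean for each of the 4 groups was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), so that the groups shared an estimate of the spread. The contrasts were H1 RNAi minus GFP RNAi in Kc cells, the glands labelled H1 RNAi minus those labelled nau RNAi, and the difference between these effects (gland effect minus Kc effect). The p-values were adjusted by Benjamini-Hochberg over all probe sets tested, and an adjusted p under 0.05 was called higher or lower. Data were simulated for 18769 probe sets with 200 known changes and with the same spread of a probe set in both systems. The Kc contrast recovered 76% of 2-fold and 95% of 4-fold changes, the gland contrast 85% and 96%, and the contrast of the difference 62% and 93%. In the real data many more gland probe sets were called and the Kc spread was smaller than that of glands. These shares therefore describe the simulation and not the recovery in the real data. Signal near background was judged from 17 Tag control probe sets, which match no Drosophila transcript. Their 95th percentile was 3.55 on the log2 scale, and on average 33.8% of the tested probe sets of an array lay at or under their highest value.

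Gene lists were written from textbook knowledge before the data were examined, as were the groups, the tests, the rule for named genes and the alternatives unless stated otherwise. The lists were H1 target genes, core histone repeat genes, histone variants, heterochromatin proteins, pericentric heterochromatin resident genes, chromosome 4 genes, piRNA and siRNA silencing genes, salivary gland secretion genes, ecdysone response genes, apoptosis, DNA damage, DNA replication and mitosis genes, immune peptide and recognition genes, heat shock genes, JNK and JAK-STAT genes, glutathione transferase and P450 detoxification genes, testis and germline genes, ribosomal protein genes, ribosome biogenesis genes, Polycomb and Trithorax group genes, Hox and developmental Polycomb target genes, dosage compensation genes, chromatin assembly and remodelling genes, and markers of fat body, muscle, haemocytes, neurons and glia, trachea and epidermis, midgut and imaginal cells. A list of transposon-encoded genes is not analysed here. The 29 lists with at least 3 measured members were tested over all named genes with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, which asks whether the members move one way on balance and does not compare them with other genes. List p-values were adjusted over the 29 lists within a contrast. Members were also counted after adjustment over the list alone.

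The genes named for Kc cells and for glands were nau, the H1 and core histone probe sets, the 10 highest and the 10 lowest fold changes among called genes whose H1 RNAi arrays all lay on one side of all control arrays, and at most 4 members of each list, those with the largest change among the called members or otherwise those with the smallest p. For the difference between systems, the 5 highest and the 5 lowest called genes were named. Overlap of calls between the systems was tested with a two-sided Fisher's exact test on named genes, and fold changes were correlated across genes, which are not independent replicates. The numbers of neighbouring genes called in the same direction were compared with 10000 random draws of as many genes.

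The alternatives were a fit of each system alone, eBayes with trend and robust settings, removal of the 40% of probe sets with the lowest mean, a further quantile normalization, median centring, a mean over the probe sets of a gene, an added 2-fold threshold, the array letter as a block, and each array left out in turn. Removal of probe sets at the level of the Tag controls in every group and an exchange of the gland labels for the difference between systems were added after the data were seen. With 2 or 3 arrays per group, no test of outlying arrays was run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.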

Results

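The data set compared RNAi against the linker histone H1, which binds the DNA between nucleosomes, with a control RNAi in a cell line and in a tissue. Kc cells received dsRNA against H1 or against GFP, with 2 arrays per group. Salivary glands, whose cells have polytene nuclei and secrete the glue proteins of the larva, came from flies labelled H1 RNAi or nau RNAi, with 3 arrays per group. Gene signals were log2 intensities, and the highest value of an array lay between 14.09 and 14.34, so that levels close to it cannot rise further. Arrays of a group correlated with r = 0.9983 in both Kc groups and with r from 0.9886 to 0.9937 in the gland groups. The pooled standard deviation within a group was 0.114 and 0.117 in Kc cells and 0.238 and 0.263 in glands. The first principal component, with 79.7% of the variance, separated glands from Kc cells, and the second, with 15.1%, separated the glands labelled H1 RNAi from those labelled nau RNAi.

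The targets of the RNAi came first. No probe set used here is named for the His1 genes, so the depletion of H1 itself was not measured. BigH1, the germline variant of H1, had low signal and did not pass the test in Kc cells (log2 change -0.16, adjusted p = 0.651) or in glands (0.16, adjusted p = 0.216). The core histone repeat genes were represented by 1 His2A family probe set, which did not pass either (Kc -0.08, adjusted p = 0.973; glands 0.09, adjusted p = 0.772). The transcript of nau, a myogenic transcription factor, was 5.68 ± 0.29 (SD, n = 3) in the glands labelled nau RNAi and 3.47 ± 0.10 (n = 3) in those labelled H1 RNAi (adjusted p = 1.26e-06). This is opposite to a depletion of nau in the glands labelled nau RNAi. Whether RNA of the RNAi construct adds to the signal of the probe set was not tested, so every gland direction below refers to the labels. In Kc cells, where nau was not a target, its signal rose from 5.96 ± 0.09 (n = 2) to 7.02 ± 0.02 (n = 2) with H1 RNAi (adjusted p = 0.00632). That Kc call was lost without Kc GFP array a, H1 array a or H1 array b.

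The Kc comparison asked which transcripts change in a dividing cell line that receives dsRNA against H1. The haemocyte genes He and eater were among the largest decreases, while 10 of 12 haemocyte markers did not pass. He, a surface protein gene of haemocytes, fell from 7.32 ± 0.13 (SD, n = 2) to 3.86 ± 0.05 (n = 2), a log2 change of -3.46. Eater, a phagocytosis receptor encoded by eater, fell by 2.02 on the log2 scale, NimB5 of the Nimrod family fell by 2.43, and the growth factor gene Pvf1 fell by 2.14. Among the increases, the collagen gene Mp rose by 3.51 (standard error 0.172, 11.4-fold), the gap junction gene Inx3 by 2.99, the transporter gene Mdr49 by 2.83 and the transferrin gene Tsf1 by 2.72.

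In all, limma called 771 of 18769 probe sets (4.11%) in Kc cells, 543 higher and 228 lower, and these represented 414 genes higher and 190 lower. At least a 2-fold change was found for 269 of the higher and 36 of the lower probe sets. The H1 and GFP arrays did not overlap for 54.9% of the probe sets, where chance gives 33.3% for 2 arrays against 2. The other genes with the largest increases were CG5111 (3.50), CG12535 (3.19), the myosin gene Myo28B1 (3.14), Taf12L (3.08, adjusted p = 0.0333), which encodes a relative of a general transcription factor subunit, CG31272 (2.87) and narya (2.64), a gene of meiotic recombination. The other large decreases were those of CBP (-2.35, adjusted p = 0.0377), CG14340 (-1.85), Faa (-1.81), a gene of tyrosine breakdown, Sid (-1.79), the forkhead gene fd59A (-1.69) and CG44433 (-1.50). The GFP means of CG5111 and Taf12L lay under the 95th percentile of the Tag controls (3.55), so their increases are lower bounds. The adjusted p of these genes and of those named before ranged from 2.57e-05 for Mp and Inx3 to 0.0377 for CBP.

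Detoxification genes were the list with a camera call among the 29 tested in Kc cells (adjusted p = 7.67e-05). The call was lost with an estimated correlation (adjusted p = 0.954 with an estimated correlation) and was not made by fry (adjusted p = 0.19). Of its 41 measured members 4 rose over all genes tested, the P450 genes Cyp6d5 (2.23), Cyp12d1-d (1.62) and Cyp6d2 (1.43) and the glutathione transferase gene GstS1 (0.90). Adjusted over the list alone, 11 members were higher and 1 was lower. Of 49 chromosome 4 genes 4 rose and none fell, namely dati (2.24), the Hedgehog pathway transcription factor ci (1.74), CG31999 (1.51) and CG1909 (0.57, from background level), with a camera adjusted p of 0.128. CG40006 (1.58) was the call among 31 pericentric heterochromatin residents (camera adjusted p = 0.598), and none of 23 heterochromatin proteins passed in limma (camera adjusted p = 0.859), with 2 at an unadjusted p under 0.05. Of 12 haemocyte markers He and eater fell and 10 did not pass (camera adjusted p = 0.544).

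Other lists held a few calls each in Kc cells. The tumour suppressor gene p53 rose (0.73) and the recombination gene okr fell (-0.46) among 25 DNA damage genes (adjusted over the list alone, 2 higher and 1 lower; camera adjusted p = 0.247). The TNF gene egr (-0.51) and the caspase gene Dredd (-0.47) fell among 16 apoptosis genes (camera adjusted p = 0.859). The germline Argonaute gene piwi rose (0.70) among 29 silencing genes (0.859), Sgs5bis (0.93) and the gland transcription factor sage (0.69) rose among 24 salivary gland secretion genes (0.858), and Cyp18a1 (1.10), which inactivates ecdysone, rose among 27 ecdysone response genes (0.509). Drsl2 (0.98) and PGRP-LB (0.76) rose among 25 immune genes (camera adjusted p = 0.735), Pvf1 was the decrease among 17 JNK and JAK-STAT genes (0.859), and Psc (0.74) rose among 26 Polycomb and Trithorax group genes (0.859). The egg-polarity gene bcd (1.49), swa (0.71) and tomb (0.57) rose and gcl (-0.61) fell among 39 testis and germline genes (camera adjusted p = 0.598). Among cell type markers, Apoltp (1.09, 1 of 8 for fat body, 2 higher when adjusted over the list alone; camera adjusted p = 0.544), the calcium channel gene cac (0.78, 1 of 11 for neurons and glia, 1 higher and 1 lower when adjusted over the list alone; 0.646), Cpr49Ae (2.17, 1 of 9 for trachea and epidermis; 0.363) and bab2 (1.01, 1 of 9 for imaginal cells; 0.509) rose.

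No member of 11 further lists passed in limma, and the number at an unadjusted p under 0.05 is given for each. It was 1 of 3 histone variants (adjusted over the list alone, 1 lower; cal1 -0.34, adjusted p = 0.0902), 2 of 33 DNA replication genes (Rbf 0.31, adjusted p = 0.209), 0 of 27 mitosis genes (Cap-G 0.22, adjusted p = 0.483), 1 of 8 heat shock genes (Hsc70-3 -0.33, adjusted p = 0.107), 2 of 41 ribosomal protein genes (RpS19b -0.52, adjusted p = 0.0942) and 3 of 26 ribosome biogenesis genes (Non1 -0.27, adjusted p = 0.25). It was 1 of 35 Hox and Polycomb target genes (Dfd 0.36, adjusted p = 0.315), 1 of 7 dosage compensation genes (mof 0.29, adjusted p = 0.281), 0 of 18 chromatin assembly genes (Chd1 0.24, adjusted p = 0.352), 2 of 10 muscle markers (Mlc2 0.82, adjusted p = 0.279) and 2 of 11 midgut markers (Jon44E -0.29, adjusted p = 0.181). Their camera adjusted p ranged from 0.467 for ribosome biogenesis to 0.917 for midgut markers. Where no other count is given for Kc cells, the count adjusted over the list alone equalled that over all genes.

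The 18S rRNA control probe set was 8.04 ± 1.41 (n = 2) in the GFP arrays and 5.40 ± 0.54 (n = 2) in the H1 arrays, and the Bacillus control transcripts averaged 5.07 ± 0.55 and 4.06 ± 0.13. Both were lower in each H1 array than in each GFP array, while the E. coli and P1 controls were at 9.685 and 9.652. The shift of the 18S and Bacillus signals goes with the label, so its part in the Kc calls cannot be told apart from the RNAi. The number of Kc calls fell to 289 without GFP array a, 284 without GFP array b, 316 without H1 array a and 274 without H1 array b, and was 2152 when Kc cells were fitted alone. Among the named Kc genes, Taf12L, CBP, p53, okr, egr, Dredd, piwi, sage, Sgs5bis, Drsl2, PGRP-LB, Psc, bcd, swa, tomb, gcl, Apoltp, cac, bab2, dati and CG1909 lost their call without at least 1 of the 4 Kc arrays.

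In salivary glands, the comparison asked the same of a differentiated polytene tissue raised under RNAi from the embryo on. Sgs1 and Sgs4, which encode proteins of the glue that fixes the pupa to its substrate, were far lower in the glands labelled H1 RNAi. Sgs1 was 11.92 ± 0.16 (SD, n = 3) in the glands labelled nau RNAi and 5.33 ± 0.71 (n = 3) in those labelled H1 RNAi, and Sgs4 was 14.28 ± 0.05 and 9.32 ± 0.87. Among single genes of DNA repair, silencing and detoxification, large increases were found. Mre11, a nuclease of double-strand break repair encoded by mre11, rose from 5.33 ± 0.15 to 9.18 ± 0.16, the piRNA gene del from 3.11 ± 0.28 to 7.61 ± 0.37 and GstE6 from 6.71 ± 0.18 to 12.16 ± 0.16.

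The limma fit called 7631 of 18769 probe sets (40.7%) in glands, 3525 higher and 4106 lower. These represented 2824 genes higher and 2827 lower, of which 187 rose and 55 fell by at least 8-fold. Each direction held 23.6% of the 11982 named genes, and the list counts below are to be read against that share. At least a 2-fold change was found for 1478 of the higher and 845 of the lower probe sets, so the larger side depended on the threshold. The arrays of both groups did not overlap for 49.0% of the probe sets, where chance gives 10% for 3 arrays against 3. The largest increases were those of CG13135 (8.09, standard error 0.127, adjusted p = 8.66e-10), Taf12L (7.58), CG8620 (7.33), CG14545 (7.30), the odorant binding protein gene Obp50e (7.02), lncRNA:CR42646 (6.92), CG12493 (6.88), the planar polarity cadherin gene stan (6.83), Marf1 (6.81), a regulator of mRNA stability in the germline, and blanks (6.62), which encodes a binder of double-stranded RNA. Their adjusted p did not exceed 3.67e-06. The largest decreases were those of Sgs1 (-6.59, standard error 0.288), SmydA-9 (-5.59), Sgs3 (-5.40), Eig71Eg (-5.22), Npc2e (-5.15), CG34276 (-5.13), CG9812 (-4.98), Sgs4 (-4.95), CG13101 (-4.86) and the scavenger receptor gene santa-maria (-4.79). The changes of CG14545, Obp50e, lncRNA:CR42646, stan, Eig71Eg and Npc2e are lower bounds, since 1 group mean lay under the 95th percentile of the Tag controls (3.55). Those of Sgs3 and Sgs4 are lower bounds of the fall, since their means in the glands labelled nau RNAi, 14.21 and 14.28, lay near the top of the array range. Sgs3 had the widest spread of these, with 9.87, 11.39 and 5.15 in the 3 arrays labelled H1 RNAi (adjusted p = 0.00597).

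**Figure D1:**
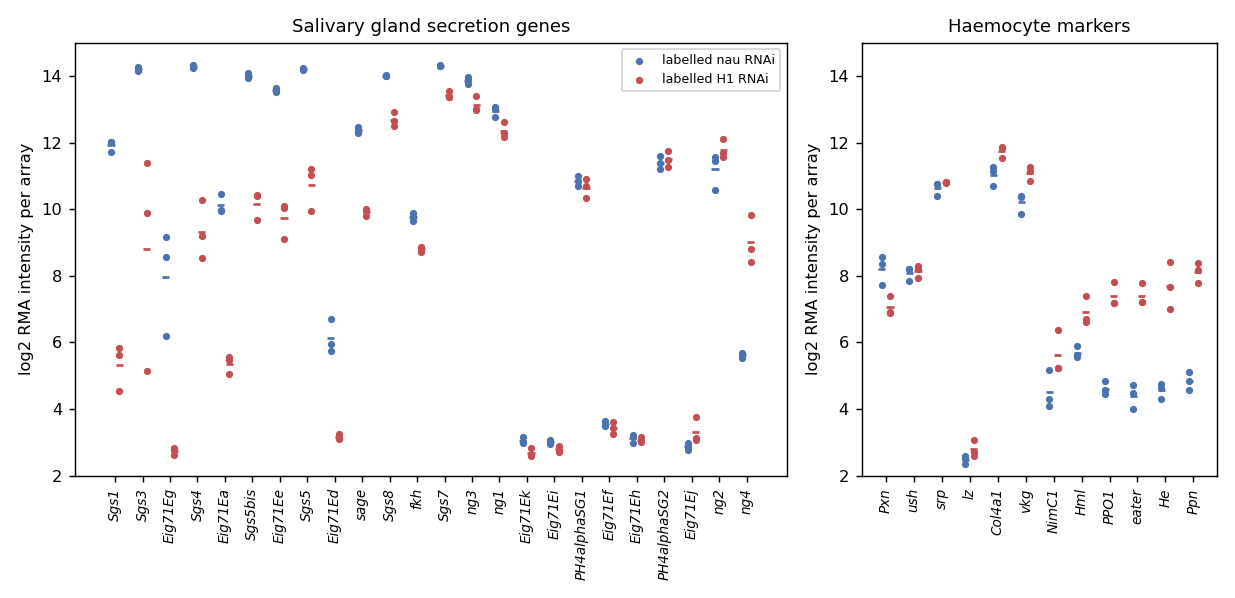
Log2 RMA intensity of each salivary gland array for the members of the secretion gene list and of the haemocyte marker list, with the arrays labelled nau RNAi in blue, those labelled H1 RNAi in red and a bar at each group mean. Sgs1 lay at 11.92 and 5.33 on average in the groups labelled nau RNAi and H1 RNAi, and He at 4.56 and 7.69.

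Of 24 measured salivary gland secretion genes 16 fell and 1 rose (adjusted over the list alone, 17 lower and 2 higher; camera adjusted p = 6.86e-05). With an estimated correlation the call was lost (adjusted p = 0.0573 with an estimated correlation). The transcription factor sage fell by 2.45 and fkh by 0.97, while the increase was that of ng4 (3.39). PH4alphaSG1 (-0.20, adjusted p = 0.3) and PH4alphaSG2 (0.10, adjusted p = 0.579), which encode gland prolyl hydroxylases, did not pass. Of 27 ecdysone response genes 12 fell and 1 rose (camera adjusted p = 0.0824), among them Eip78C (-2.88), Hr4 (at least 2.75 lower) and Hr39 (-1.43), which encode nuclear receptors, and the transporter gene E23 (-2.68). Single arrays labelled nau RNAi differed in these genes, with 6.02, 4.90 and 7.85 for Hr4 and 5.69, 5.84 and 7.80 for Eip78C. Beside these decreases, the log2 signal difference between 3′ and 5′ control probe sets, a measure of RNA degradation and of incomplete labelling, was higher in the glands labelled H1 RNAi. It was 1.92 ± 0.10 (n = 3) and 2.29 ± 0.18 (n = 3) for actin, 2.13 ± 0.05 and 2.53 ± 0.09 for GAPDH, and 2.17 ± 0.09 and 2.48 ± 0.07 for eIF-4a, in the order nau and H1, and all 3 H1 arrays exceeded all 3 nau arrays for each.

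DNA damage genes had the smallest camera p in glands (adjusted p = 1.49e-10), and this call was lost with an estimated correlation (adjusted p = 0.0573 with an estimated correlation). Of 25 members 21 rose and 1 fell, with a median log2 change of 1.49. They included mre11 (3.86), Irbp (3.83) and Ku80 (3.39), which encode the Ku heterodimer of end joining, and the alkyltransferase gene agt (3.12). Of 29 silencing genes 20 rose and 2 fell (camera adjusted p = 2.4e-06; adjusted p = 0.216 with an estimated correlation), including the piRNA pathway genes del (at least 4.50), spn-E (3.76), BoYb (at least 3.74) and mael (3.60), where del and BoYb lay at background in the glands labelled nau RNAi. Of 41 detoxification genes 28 rose and 3 fell (camera adjusted p = 2.4e-06; adjusted p = 0.287 with an estimated correlation), with GstE6 (5.44), GstE5 (4.86), GstD5 (4.35) and Cyp6a23 (4.02) as the largest changes.

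Of 26 ribosome biogenesis genes 20 rose and 2 fell (adjusted over the list alone, 21 and 2; camera adjusted p = 0.000284; adjusted p = 0.682 with an estimated correlation). Among them ppan rose by 1.82, the RNA polymerase I gene Polr1B by 1.35 and l(1)G0020 by 1.25, while Mnt, a Myc antagonist, changed by -1.49. Of 27 mitosis genes 17 rose and 3 fell (adjusted over the list alone, 18 and 3; camera adjusted p = 0.00204; adjusted p = 0.682 with an estimated correlation), including borr (2.30) and Incenp (2.14) of the chromosomal passenger complex and thr (1.76) and pim (1.74), which encode separase and securin. Of 33 DNA replication genes 13 rose and 5 fell (camera adjusted p = 0.143, or 0.0288 without array a labelled nau RNAi), with RfC4 (1.81), RPA2 (1.56) and PCNA (1.49) higher and the origin recognition gene Orc1 (-1.60) lower.

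Of 12 haemocyte markers 8 rose and 1 fell (camera adjusted p = 0.0026; adjusted p = 0.216 with an estimated correlation). The matrix protein gene Ppn rose by 3.29, He by 3.14, the prophenoloxidase gene PPO1 by 2.78 and eater to a level of 7.40 ± 0.33 (SD, n = 3), while Pxn changed by -1.15. None of the 12 stood in another list, and 11 lay above the level of the Tag controls in the glands labelled nau RNAi. Markers of other cell types moved in part with them. Of 11 neuron and glia markers 6 rose and 1 fell (camera adjusted p = 0.0762, or 0.0262 without array b labelled H1 RNAi), with Appl at 2.39, cac at 2.18 or more, elav at 2.05 and Nrt at 1.30 or more, and array a labelled H1 RNAi stood out with 7.78 for elav against 5.41 and 5.68 in arrays b and c. Of 11 midgut markers 3 rose and 2 fell (adjusted over the list alone, 4 and 2; camera adjusted p = 0.349), with Jon65Aiii (1.64), Jon99Ci (1.35) and mex1 (at least 0.69) higher and Npc2d lower within the range of background. Of 10 muscle markers 3 rose and 1 fell (adjusted over the list alone, 6 and 1; camera adjusted p = 0.261), with Act79B (1.76), Mlc2 (1.21), bt (0.84) and sls (-3.63).

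Of 8 fat body markers 4 rose and 2 fell (camera adjusted p = 0.426), with bgm (2.21), Apoltp (1.53), Fbp1 (-0.58) and Fatp (-0.49). The storage protein gene Lsp2, at 14.06 and 14.08, lay near the top of the array range in both gland groups. Of 9 trachea and epidermis markers TwdlG (at least 0.54) rose and Ddc (-0.91) fell (adjusted over the list alone, 1 higher and 0 lower; camera adjusted p = 0.723), and of 9 imaginal cell markers bab2 (0.67) rose and ct (-0.89) and nub fell (camera adjusted p = 0.81), the latter within the range of background. A further probe set of ct was called in the opposite direction.

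Chromatin genes went both ways, as named genes in general did. Of 18 chromatin assembly and remodelling genes 9 rose and 3 fell (adjusted over the list alone, 10 and 3; camera adjusted p = 0.222), led by Ssrp (2.25) and dre4 (1.36), which encode the histone chaperone FACT, Chd3 (2.16) and the histone chaperone gene asf1 (1.40). Of 23 heterochromatin proteins 3 rose and 6 fell (camera adjusted p = 0.723), with HP6 (2.86), the kinase gene JIL-1 (-1.89), Sirt1 (-1.34) and Su(var)2-10 (-1.22). Of 26 Polycomb and Trithorax group genes 5 rose and 11 fell (adjusted over the list alone, 5 and 12; camera adjusted p = 0.143), with escl (2.20), trr (-0.98), osa (-0.97) and trx (-0.87). Of 35 Hox and Polycomb target genes 8 rose and 3 fell (camera adjusted p = 0.143), with cad (3.01), drm (at least 2.56), dac (at least 1.71) and Dr (-1.27). Of 7 dosage compensation genes 4 fell, mle (-1.12), Clamp (-0.58), msl-2 (-0.57) and msl-1 (-0.49), and none rose (camera adjusted p = 0.126). Of 3 histone variants and centromere genes His2Av rose (0.50) and cal1 fell (-0.62), with a camera adjusted p of 0.81.

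Genes that reside in heterochromatin went both ways in glands, as did all named genes, with 23.6% higher and 23.6% lower. Camera called neither list of them, while fry called pericentric residents (adjusted p = 2.58e-05) and chromosome 4 genes (adjusted p = 0.00339) upward. Of 31 pericentric residents 9 rose and 5 fell (adjusted over the list alone, 10 and 6; camera adjusted p = 0.143), but some increases were large, namely Marf1 (6.81), the synaptic gene Snap25 (at least 5.08), CG40006 (4.84) and AGO3 (3.52). Of 49 chromosome 4 genes 17 rose and 13 fell (adjusted over the list alone, 19 and 14; camera adjusted p = 0.264), with the eye selector gene toy (at least 4.59), unc-13 (3.64), CG31999 (3.12) and CG1909 (3.04) as the largest changes.

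Of 16 apoptosis genes 4 rose and 5 fell (camera adjusted p = 0.81), with the effector caspase gene Dcp-1 at 4.02, the apoptosome gene Dark at -2.01 and the Bcl-2 family genes Buffy and Debcl at -1.96 and 1.05. Of 25 immune genes 9 rose and 5 fell (camera adjusted p = 0.264), including the attacin gene AttD (6.19), TotC (5.87), BomS2 (3.01) and Drsl5 (-2.72). Of 17 JNK and JAK-STAT genes 5 rose and 3 fell (camera adjusted p = 0.894), with cher (-2.33), scaf (1.38), hep (-1.19) and msn (0.91). Of 8 heat shock genes Hsp68 (1.38) and Hsc70-4 (0.56) rose and Hsp27 (-0.80) fell (camera adjusted p = 0.723), and none of 4 Hsp70 family probe sets passed, with adjusted p from 0.269 to 0.963. Of 39 testis and germline genes 4 rose and 7 fell (camera adjusted p = 0.514), with bcd (2.59), ovo (1.42), gcl (-1.18) and mia (-0.61). Of 41 ribosomal protein genes 4 rose and 5 fell (adjusted over the list alone, 4 and 3; camera adjusted p = 0.936), with RpLP0-like (0.95), RpL22-like (0.94), RpL7-like (0.73) and RpS19b (-0.61).

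Camera called 7 of the 29 lists in glands and fry called 22, while 0 were called with an estimated correlation, where 5 had an unadjusted p under 0.05. For gland lists with no other count given, the count adjusted over the list alone equalled that over all genes. The calls of BomS2, Drsl5, scaf, Hsp68, msl-2, Nrt, Jon65Aiii, Npc2d, Ddc and nub were lost without at least 1 of the 6 gland arrays.

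**Figure D2:**
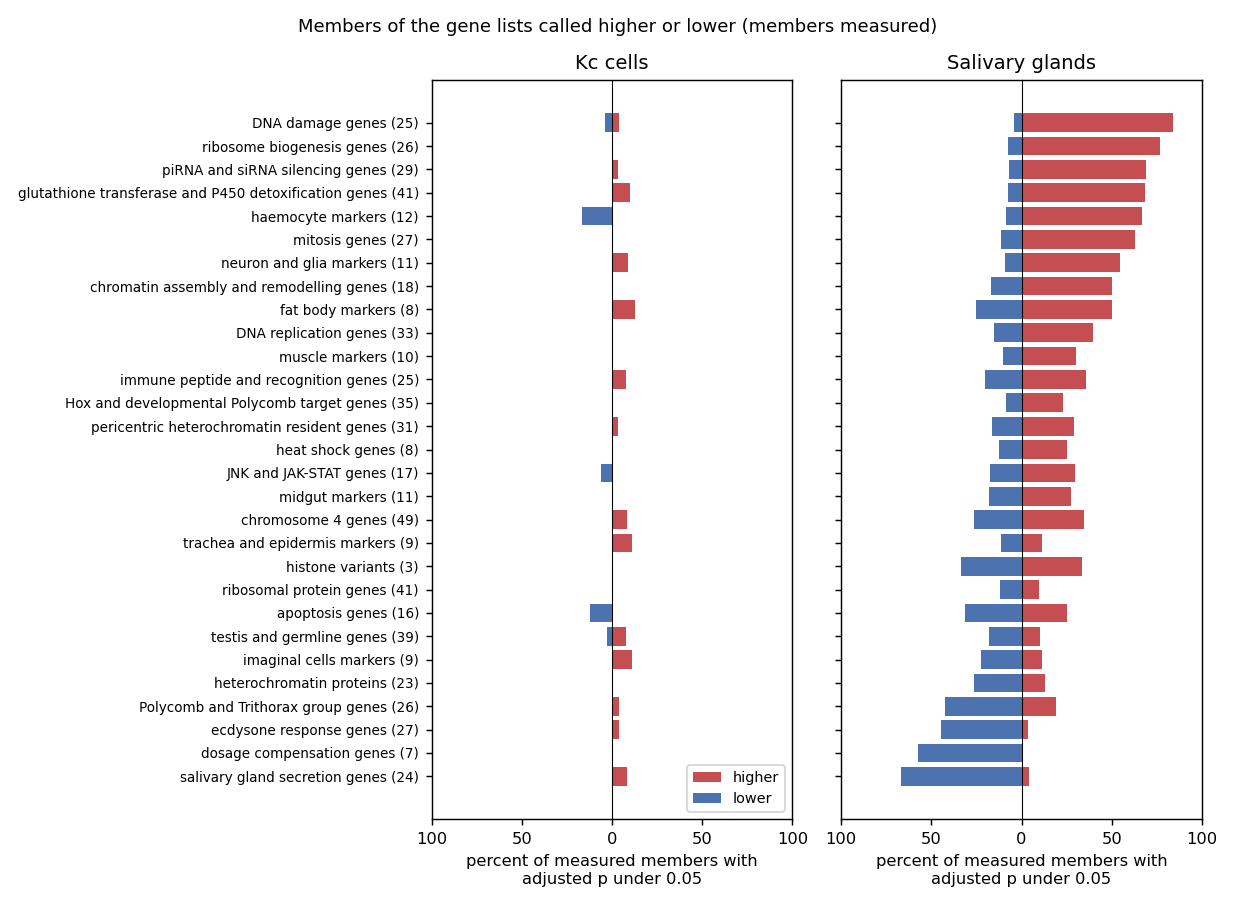
Percent of the measured members of each gene list called higher (red, to the right) or lower (blue, to the left) with an adjusted p under 0.05 in Kc cells and in salivary glands, with the number of measured members in brackets. Of 25 DNA damage genes 21 were higher in glands, and of 24 salivary gland secretion genes 16 were lower.

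The difference between the gland effect and the Kc effect was tested directly, although the control RNAi, the way of delivery and the tissue differ together. The 3′ minus 5′ control signal differed as well. For actin it was 0.44 and 0.27 in Kc cells (GFP and H1) and 1.92 and 2.29 in glands (nau and H1). In glands its shift goes with the label, so its part in the gland calls and the difference calls cannot be told apart from the RNAi. It was called for 4855 of 18769 probe sets, 2500 in the positive and 2355 in the negative direction. The larger side depended on the scaling, with 2203 positive and 2646 negative after a further quantile normalization and 2336 and 2409 after median centring. The highest fitted differences were those of CG13135 (8.22), CG14545 (7.13), Obp50e (7.05), lncRNA:CR42646 (7.03) and stan (6.88), and the lowest were those of Sgs1 (-6.29), SmydA-9 (-5.35), Npc2e (-5.34), santa-maria (-5.29) and Eig71Eg (-5.11), with adjusted p of at most 0.00322. The values for CG14545, Obp50e, lncRNA:CR42646, stan, Npc2e and Eig71Eg carry the limit of their gland changes at background, so their order is not a ranking. The haemocyte genes He and eater, lower in Kc cells and higher in the glands labelled H1 RNAi, differed by 6.60 and 5.02. Camera called 8 lists for the difference. DNA damage genes (20 positive and 1 negative of 25; adjusted p = 6.58e-10; adjusted p = 0.0666 with an estimated correlation), silencing genes (17 and 2 of 29, 18 and 2 adjusted over the list alone; 4.56e-06; adjusted p = 0.223 with an estimated correlation), ribosome biogenesis genes (12 and 1 of 26, 19 and 2 adjusted over the list alone; 0.000157; adjusted p = 0.78 with an estimated correlation) and haemocyte markers (6 and 1 of 12; 0.00403; adjusted p = 0.223 with an estimated correlation) had more positive differences. The same held for mitosis genes (10 and 3 of 27; 0.00758) and detoxification genes (15 and 6 of 41, 16 and 8 adjusted over the list alone; 0.0209), each with an adjusted p = 0.78 with an estimated correlation. Secretion genes (1 and 12 of 24, 1 and 13 adjusted over the list alone; 5.81e-05; adjusted p = 0.0666 with an estimated correlation) and ecdysone response genes (0 and 10 of 27, 0 and 14 adjusted over the list alone; 0.0245; adjusted p = 0.459 with an estimated correlation) had more negative ones.

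Some genes were called in one direction in both systems. Of 414 genes higher in Kc cells 169 were also higher in glands, where independent lists would share 97.6 (odds ratio 2.32, two-sided Fisher's exact p = 2.69e-15). Of 190 genes lower in Kc cells 92 were also lower in glands, where independent lists would share 44.8 (odds ratio 3.11, two-sided Fisher's exact p = 7.2e-14). The opposite directions were found for 74 genes higher in Kc cells and lower in glands, against 97.7 for independent lists (odds ratio 0.697, exact p = 0.00466), and for 48 genes lower in Kc cells and higher in glands, against 44.8 (odds ratio 1.10, exact p = 0.605). These 4 tests treat genes as independent and include dim genes. With the 40% of probe sets with the lowest mean left out, the odds ratios were 1.69 for genes higher in both and 2.03 for genes lower in both. Genes chosen after the data were seen, by the smaller of both changes, show the shared part. Taf12L, Tsf1, CG34002, Mp, sano, Gyg, CG10089 and Cpr72Ec rose in both systems by at least 1.95, and the lower genes included CG3376 (-1.47 in Kc cells and -1.60 in glands), Faa (-1.81 and -1.16), wake (-1.19 and -3.39), Pgant9 (-0.91 and -3.68), which encodes a mucin glycosyltransferase, and ncm (-0.85 and -2.36). Across 11982 genes the fold changes of both systems correlated with r = 0.132 (Spearman rho = 0.095), and across the 604 genes called in Kc cells with r = 0.277 (rho = 0.273). The odds ratio for genes lower in both was 1.19 (p = 0.571) without Kc GFP array a, 1.04 (p = 0.831) without GFP array b, 1.66 (p = 0.132) without H1 array a and 1.34 (p = 0.526) without H1 array b, by exact tests.

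**Figure D3:**
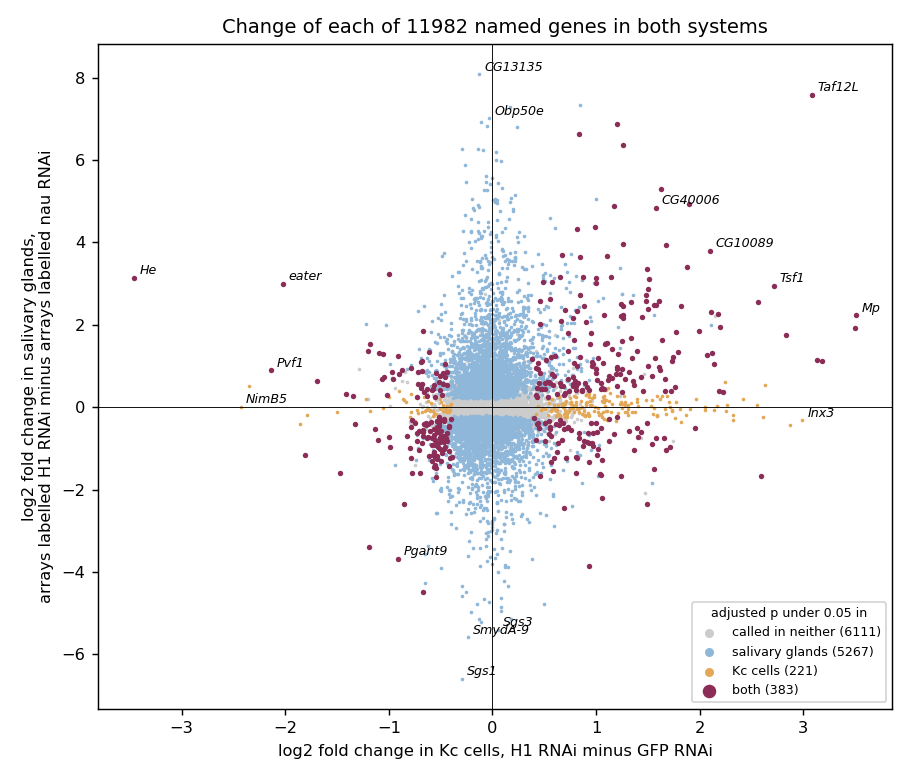
Log2 fold change of each of 11982 named genes in Kc cells (horizontal axis, H1 RNAi minus GFP RNAi) and in salivary glands (vertical axis, labelled H1 RNAi minus labelled nau RNAi), coloured by the comparison in which the adjusted p was under 0.05. He and eater lie at the upper left, Taf12L, Mp and Tsf1 at the upper right, and Sgs1 at the bottom near 0 on the Kc axis.

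Called genes also lay next to each other more often than random draws did. In Kc cells 38 pairs of neighbouring genes were called in one direction, against a mean of 17.3 in 10000 random draws (middle 95% from 10 to 26), and in glands 1611 pairs against 1329 (1271 to 1387). With at least a 2-fold change the numbers were 16 against 3.64 in Kc cells and 239 against 152.1 in glands. The two-sided p was 0.0002 in each of the 4 tests, the smallest that the draws can give. The draws ran over all placed genes, dim ones included, and made no allowance for neighbouring members of a gene family. How far these account for the excess was not tested.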

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

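The tests of the small decreases, of the secretion genes and of the haemocyte markers were chosen only after the results were seen, as were the ranges of signal used in them and the exchange of the gland labels, and only the count of splits was planned. The effect of H1 RNAi differed between glands and Kc cells for 4855 probe sets by a test of the difference itself. That difference was 6.60 for He and 5.02 for eater on the log2 scale, with a decrease in Kc cells and an increase in the glands labelled H1 RNAi. These directions rest on the gland labels, against which the nau signal stood, although RNA of the nau construct may itself give that signal, which was not tested. With the labels of both gland groups exchanged, 5414 probe sets were called for the difference, He and eater were lower in both systems, and their differences were 0.32 (adjusted p = 0.642) and -0.97 (adjusted p = 0.0423). By the labels as given, 74 genes were higher in Kc cells and lower in glands, against 97.7 for independent lists. A further 48 were lower in Kc cells and higher in glands, against 44.8. In one direction were 169 genes higher in both, against 97.6, and 92 lower in both, against 44.8. The last excess did not pass with the array letter as a block (odds ratio 1.705, exact p = 0.0628). The exchange would turn these shared directions into opposite ones, so it does not bring the systems together in general. A control probe set not resolved to a transcript here, and left out of the gene tests, was higher in the glands labelled nau RNAi than in the GFP-treated Kc cells by 4.34 on the log2 scale, at 7.76 ± 0.07 (SD, n = 3) against 3.41 ± 0.165 (n = 2). It was 6.08 ± 0.26 (n = 3) in the glands labelled H1 RNAi, a change of -1.68 (adjusted p = 3.9e-05 in a limma fit of the control probe sets). It may measure yeast GAL4, the driver of the gland RNAi, which was not checked here; the driver level would then differ between the gland groups. The real grouping of the 6 gland arrays gave 7631 calls in limma, and 1 of 10 splits gave as many, the real one. The highest of the other splits gave 0 calls, with 499 to 913 probe sets at an unadjusted p under 0.05, but 10 splits are too few for a share under 0.05.

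Glands labelled H1 RNAi had 3261 probe sets lower and 2047 higher by less than 2-fold. A shift limited to probe sets at the level of the Tag controls would need most of the small decreases to lie there, and 13.8% of them (451) had both gland means at or under the 95th percentile of the Tag controls, against 4.35% of the small increases (89), which argues against it for most of them. A shift that reaches brighter probe sets stays open, since the control sets were lower on average in the glands labelled H1 RNAi. The Tag controls were at 2.99 ± 0.05 (n = 3) against 3.18 ± 0.03 (n = 3) and the Bacillus controls at 6.72 against 7.27. The E. coli and P1 controls were at 10.3 against 10.5, but their brightest members did not fall. The bioB controls, near 8.4 to 8.8 in the glands labelled nau RNAi, changed by -0.57 to -0.25. The bioC and bioD controls changed by -0.23 to 0.05 and the P1 cre controls, at 12.66 to 13.53, by -0.03 to 0.16. The median change was -0.0878 for probe sets at Tag level and -0.0663 above it, and the calls split into 3210 higher and 4967 lower after median centring and 3228 and 4252 after quantile normalization, against 3525 and 4106. An effect of H1 RNAi itself also stays open, as untested.

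Of 24 secretion genes 16 fell in the glands labelled H1 RNAi. If these samples only held a smaller share of gland RNA, gland genes would fall alike and keep their ratios within an array, but the ratio differed between the groups for 18 of 21 pairs (85.7%) of the 7 members with a control signal between 10 and 13 on the log2 scale (limma, adjusted p under 0.05). It differed for 78 of 105 pairs without the upper bound and for 204 of 276 pairs of all members, and ng2 (0.59, interval 0.01 to 1.18) and PH4alphaSG2 (0.10, interval -0.20 to 0.41) did not fall, which argues against a smaller gland share as the whole source. The pairs share members and are not independent. Their count restates how far the 7 changes spread, from -6.59 for Sgs1 to 0.59 for ng2. Members with transcripts from other cells as well would fall less, and this stays open. Younger glands, which may also have low glue transcripts, cannot be told apart from an effect of H1 RNAi, since the ecdysone response list was lower with a camera adjusted p of 0.0824 (0.0409 with the dimmest 40% of probe sets left out), neither under 0.05 nor above the bound of 0.5 set for this test, and the labels give no stage.

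Of 12 haemocyte markers 8 rose and 1 (Pxn) fell in the glands labelled H1 RNAi, and the camera call of the list was lost with an estimated correlation (adjusted p = 0.216 with an estimated correlation). A smaller gland share would raise the markers of every other cell type alike, and the mean changes of the 7 marker lists, from -0.03 for imaginal cells to 0.915 for neurons and glia and 1.29 for haemocytes, did not differ past the threshold (permutation p = 0.077, or 0.095 with markers under a control signal of 13), while camera called 1 of the 7 lists, where such a share was set to give at least 4. Such a share and a change of haemocyte genes alone therefore cannot be told apart, since a p above 0.05 does not show that the lists moved alike. More haemocytes on the glands would raise all haemocyte markers that Kc cells express, and 8 of 11 such markers were called higher and 1 lower, with the abundant markers Col4a1 and vkg up by 0.71 and 0.89. Attached haemocytes and expression of these genes in the gland cells cannot be told apart either, because no sample of haemocytes is part of the design.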

How the results depend on the processing

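Removal of probe sets at the level of the Tag controls and the exchange of the gland labels were chosen after the data were seen. The removal gave 836 Kc, 7385 gland and 5052 difference calls, and the exchange 5414 difference calls. The Kc count was 2152 when Kc cells were fitted alone (1275 higher and 877 lower), 305 with a 2-fold threshold, 447 with the array letter as a replicate block, and between 274 and 916 with 1 array left out, the low values without a Kc array. A lone remaining Kc array was assumed to vary like the other groups, and the higher count of the separate fit comes with a spread estimated from Kc arrays alone. The gland count was 6340 when glands were fitted alone (3038 higher and 3302 lower), so the gap between the systems was smaller with separate fits. It was 2323 with a 2-fold threshold and 6854 to 7315 with 1 array left out. The count for the difference was 2387 with a 2-fold threshold and 4520 to 5048 with 1 gland array left out. Each fit without a Kc array gave a lower count than these gland leave-outs, with 1 array left in that Kc group. In the settings that keep single probe sets, shared calls did not change direction, with the difference not fitted when systems were fitted alone. Only rescaling or leaving out an array could change a direction there, since the other settings keep the fold changes as they are. Deviations of same-letter arrays correlated weakly, with r = -0.0722, 0.0892 and 0.0655 for a, b and c in glands and -0.00319 in Kc cells. Gland arrays b and c correlated best with their own letter and arrays a did not. Whether the letters pair the arrays is therefore not settled. The replicate block gave 7147 gland and 4269 difference calls. The odds ratio for genes lower in both systems was 1.705 with the replicate block (exact p = 0.0628) and 1.043 to 3.216 with 1 array left out. For genes higher in both it stayed past its threshold in every setting run (2.100 to 2.554 with 1 array left out). With the dimmest 40% of probe sets left out it was 1.69 for genes higher in both and 2.028 for genes lower in both. Without probe sets at Tag control level in every group it was 1.762 and 2.345, so part of the excess came with dim genes. The correlation across genes was 0.139 after a further quantile normalization, 0.123 with the mean over the probe sets of a gene, and 0.122 to 0.142 with 1 array left out; its spread was taken as the standard deviation over these. The neighbour counts kept their side of the threshold with a 2-fold minimum. Among the 58 list results of Kc cells and glands, 8 lost their call with an estimated correlation; under fry 14 gained and 1 lost it. The JNK and JAK-STAT list in glands turned from upward and not called to downward and called under fry (median change 0.00373, adjusted p = 0.00427); its members go both ways and fry does not compare them with other genes. In the other settings no list lost its call, and 2 gained one with the dimmest 40% of probe sets left out (chromosome 4 in Kc cells, adjusted p = 0.0283, and ecdysone response in glands, 0.0409), 2 with quantile normalization (Polycomb and Trithorax group, 0.0466, and dosage compensation in glands, 0.0476) and 2 with 1 array left out (DNA replication, 0.0288, and neuron and glia markers in glands, 0.0262). Of 233 single-gene results, 42 missed a 2-fold threshold, 16 lost their call with the replicate block, 9 with quantile normalization, 9 with trend and robust settings, 6 of 223 when systems were fitted alone, 3 with gene means, 1 with median centring and 32 with at least 1 array left out, and none reversed. A reversal was possible only with rescaling, gene means or an array left out. For results that were never called, a change of sign was not counted. For the moved values without a stated reason the cause was not tested. Signal over background limits the dim genes, since on average 33.8% of the tested probe sets of an array lay within the range of the Tag controls.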

Other observations

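The test of the genes raised by at least 8-fold, and the gene families grouped here by symbol, were chosen only after the results were seen. All 13 measured genes of the Turandot and Bomanin families, which encode small secreted stress and immune peptides, were called higher in the glands labelled H1 RNAi, with a median change of 4.77 (camera adjusted p = 2.76e-06 over 24 families; adjusted p = 0.389 with an estimated correlation). They included TotB (6.28), TotC (5.87), TotZ (5.61) and BomBc2 (5.56). In Kc cells 0 of the 13 passed in limma, where the family median was -0.01. The glands labelled nau RNAi already differed in TotC, with 4.37, 9.31 and 8.84 in arrays a, b and c.

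Of 83 cytochrome P450 genes 14 were called higher and none lower in Kc cells, with a family median of 0.07 (camera adjusted p = 1.47e-05; adjusted p = 0.422 with an estimated correlation), with Cyp28d1 at 2.61 and Cyp12c1 at 2.18. In glands 40 of the 83 were higher and 7 lower (camera adjusted p = 0.000531; adjusted p = 0.389 with an estimated correlation). Of 69 mitochondrial ribosomal protein genes 38 rose and 7 fell in glands (camera adjusted p = 0.000366; adjusted p = 0.703 with an estimated correlation), while of 31 vacuolar ATPase subunit genes 17 fell and 3 rose (camera adjusted p = 0.00772; adjusted p = 0.389 with an estimated correlation). Of 11 tudor-domain genes 8 rose and 1 fell in glands (camera adjusted p = 0.00252; adjusted p = 0.389 with an estimated correlation). Of 34 glutathione transferase genes 18 rose and 5 fell in glands (camera adjusted p = 0.00185; adjusted p = 0.389 with an estimated correlation). These P450, transferase and tudor families share members with the detoxification and silencing lists.

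Genes raised by at least 8-fold in the glands labelled H1 RNAi may be genes at background in the other glands that became measurable. Of the 187 such genes 31, or 16.6%, had a mean in the glands labelled nau RNAi at or under the 95th percentile of the Tag controls, with a median of 4.56 on the log2 scale. The bounds were at least 50% if this held for most of them and under 25% if not. The lower bound was first set lower, which left the question open, and was raised to that of the small decreases with the value known. No verdict is therefore drawn from the bounds. By count, most of the 187 genes had a mean above that level in the glands labelled nau RNAi, and the explanation stays open for the 31. Of the 55 genes lowered by at least 8-fold, 8 (14.5%) lay at that level in the glands labelled H1 RNAi.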
